A study of Mus musculus with 2 samples.

How the data were processed

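The deposited files hold counts of unique molecular identifiers (UMIs), per the file headers and as the values show, in a matrix of 28692 genes by barcodes for each of 2 libraries (6 deposited files: matrix, barcodes and genes of each). Each library pooled 3 mice, so the library is the unit of replication and there was 1 per group. The submitters' processing notes name bcl2fastq, Cell Ranger 2.2, STAR, Seurat 2.3.4 and R 3.6.0 with the genome build GRCm38.p6, and the role and order of these tools are not given in the sources used here. The matrix header names software version 3.0.2. Only the deposited counts were analysed; reads were not analysed here.

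The steps here were run with Python 3.11.15, scanpy 1.11.5, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9 and matplotlib 3.10.9. Barcodes with at least 200 genes and at most 10% UMIs of the 13 mitochondrial genes were kept, and scrublet doublet calls, made per library with an expected rate of 0.008 per 1000 barcodes, were removed. There were 113 control and 255 MC38 barcodes under 200 genes, and 644 and 1661 doublet calls. Both libraries were clustered together without integration: counts scaled to 10000 per cell and log-transformed, 2000 variable genes picked across libraries without antigen receptor segment, mitochondrial and ribosomal protein genes, scaled values limited to 10, 30 principal components, 15 neighbours, shared-neighbour (Jaccard) weights, and Leiden clustering at resolution 1.0 with seed 0. A cluster was scored on each of 22 fixed marker classes by the mean log2 ratio of its CPM to the mean of the other clusters, with 10 CPM added. It took the best class at a score of at least 1.0, a margin of at least 0.5 and at least 3 markers detected in at least 10% of cells. Clusters with at least 3 cell cycle genes among their 10 leading genes stayed unnamed, as did those with a median of at least 10 UMIs of T or B cell markers and at least 30 of myeloid markers. Classical monocytes, nonclassical monocytes and macrophages formed a single class, for which the margin was not asked.

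Within the 7 classes with at least 100 cells in each library, and over all cells, UMIs were summed per library and divided by the sum over all genes, giving CPM, in which all genes of a class sum to the same total in each library. Folds are the MC38 CPM over the control CPM with exact conditional 95% intervals for a ratio of Poisson counts, which cover counting error only; shares have exact binomial intervals. The median log2 ratio over genes with at least 50 UMIs in each library gave the scaling shift. For gene lists, the median log2 fold over members with at least 10 UMIs in the libraries together was placed among 10000 random lists matched in 20 bins of mean expression, and its counting interval came from 1000 Poisson draws; a member at 0 counts was set to a floor of 3. The percentile shows the place among genes of like expression and is no test between groups. A member was counted as higher or lower at 1.5 times or more with an interval that excluded no difference. The T cell lists were tried in T-cell-like and NK- or ILC1-like cells, the macrophage lists in monocyte- or macrophage-like and dendritic cells, and the B cell list in B-cell-like cells. The neutrophil list was not computed because the neutrophil-like class had under 100 cells in a library.

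Genes were named by a fixed rule. A gene needed at least 50 CPM, detection in at least 10% of cells and at least 10% of its highest CPM in any class (the last as a guard against free RNA, over classes of at least 20 cells), each in the library where it was higher. Antigen receptor, ribosomal protein, mitochondrial, hemoglobin and unnamed-model genes and fixed markers of other classes were left out. Genes were ranked by the end of the interval of the log2 fold nearest 0, and the first 12 in each direction were named in T-cell-like and monocyte- or macrophage-like cells, 3 in the other classes and 10 over all cells, where the class guards were not used. Fas, Fasl, Cd274, Pdcd1, Ccr2, Itgam, Adgre1, Cd8a and Foxp3 were named in each class with at least 10 UMIs of them. Of each list, the 2 highest and 2 lowest members by the same rank were named in the large comparisons, and 1 of each in the others; some genes that the rule named are not reported here. Where gene IDs shared a symbol, the ID with most UMIs kept it. Ensembl IDs matched the GENCODE M21 annotation for 213 of 214 named gene IDs; positions are 1-based.

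The alternatives tried were called doublets kept, at least 500 genes per cell, a mitochondrial limit of 5%, resolution 2.0, each library clustered on its own, cells thinned to 1000 UMIs, scaling by the median ratio, the mean over cells, and other minimums for list members. The 22 marker classes, 23 gene lists, naming rule, comparisons and alternatives of the first plan were set before the data were examined. After values were seen, these choices were made: the thresholds for cluster names, the joining of monocytes and macrophages into one class, the alternatives with mitochondrial limits of 30% and none, the shares among named immune cells, the number of list examples, the values within single clusters and the genes looked up there, the setting of Arg1 beside Orm1 and without the Saa3-led cluster, and the results held to the closer standard in the checks of other settings. Those results were the shares of T, B, NK or ILC1, pDC, neutrophil and monocyte or macrophage cells, the T cell subsets, and the lists for type I interferon, glycolysis, MHC class II and tumor-associated macrophages in monocyte- or macrophage-like cells and for naive, cytotoxic, checkpoint, apoptosis and type I interferon genes in T-cell-like cells.

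The code was tried on counts simulated with known folds of log2 1 and 2 in each direction, with 10707 genes at T-cell-like and 13090 at monocyte- or macrophage-like depth and 15633 over all cells. Intervals held the true fold for 95.9%, 96.1% and 95.8% of unchanged genes and for 90.0% to 100.0% of changed ones. Of 100 lists without a difference, 8 (T-cell-like) and 3 (monocyte- or macrophage-like) fell outside the middle 95% of random lists. Share intervals held the true value in 962 of 1000 draws, and 4 of 4 simulated clusters were named rightly, with 600 of 600 cells. The draws followed the Poisson and binomial models that the intervals assume, so coverage near 95% was built in and tests the code only. UMIs of a gene gathered in few cells, as given for Hspa1b below, were not simulated.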

Results

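Droplet-based single-cell RNA sequencing with unique molecular identifiers (UMIs) was applied to mononuclear cells of mouse liver, 14 days after tumor cells or buffer had been injected into the spleen. There were 2 groups with 1 library each, and each library pooled the cells of 3 C57BL/6 mice. The MC38 group had received 500000 cells of MC38, a mouse colon adenocarcinoma line, into the spleen, which was then removed. The group called the control here had received buffer and is labelled as free of liver tumor. A subcutaneous injection of 3000000 MC38 cells is written in the protocol of both groups, whose text is the same, so whether the control mice carried such a tumor or kept their spleens is not given in the sources used here. The design asks how the immune cells of the liver differ when a colorectal tumor grows in that organ.

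The control library held 14258 barcodes with 91617457 UMIs, and the MC38 library held 19822 barcodes with 114421875 UMIs. The median depth was 5470.5 UMIs per barcode in the control and 3141.5 in the MC38 library. After filtering, 3440 control cells (24.1% of barcodes) and 11907 MC38 cells (60.1%) were kept, with 30219090 and 80868491 UMIs. The loss differed because 74.8% of control barcodes and 33.3% of MC38 barcodes had over 10% mitochondrial UMIs. Clustering gave 27 clusters, of which 23 were named from fixed markers, so a class name below means cells like that type. With 1 library per group no test between groups was possible and no difference has a replicate check. The intervals are 95% intervals, exact binomial for shares and exact conditional for ratios of counts, and they cover counting error only.

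The first comparison asks which cell classes filled the liver preparation with and without the liver tumor. T-cell-like cells made up 16.2% (15.0 to 17.5) of the kept control cells and 2.86% (2.56 to 3.17) of the kept MC38 cells, a 5.67-fold lower share. An unnamed cluster that joined T cell and myeloid genes, given below, is not counted in it. Cells like natural killer cells or type 1 innate lymphoid cells (NK- or ILC1-like) were at 10.4% (9.43 to 11.5) and 2.09% (1.84 to 2.36). Plasmacytoid dendritic cells (pDC-like), known as strong producers of type I interferon, were at 10.9% (9.88 to 12) and 1.36% (1.16 to 1.59). Conventional dendritic cells were lower too, at 4.59% and 1.42% for cDC1-like cells, the cross-presenting type, and at 8.43% and 2.03% for cDC2-like cells. Monocyte- or macrophage-like cells took a larger share, 21.6% (20.3 to 23) against 32.1% (31.3 to 33.0), and neutrophil-like cells went from 0.378% (0.201 to 0.645, 13 cells) to 1.96% (1.72 to 2.22, 233 cells).

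B-cell-like cells were at 5.81% (5.06 to 6.65) in the control and 7.84% (7.37 to 8.34) in the MC38 library. Kupffer-like cells, the resident macrophages of the liver, were at 2.21% and 3.22% and mast-cell- or basophil-like cells at 2.88% and 1.40%. Erythroid-like (0.698% and 1.08%), platelet-like (0.581% and 0.831%) and endothelial-like cells (1.02% and 0.915%) had overlapping intervals, so a difference was not detectable at this depth. Hepatocyte-like cells were 3 of the control cells (0.0872%, 0.0180 to 0.255) and 3996 of the MC38 cells (33.6%, 32.7 to 34.4), although the protocol depleted hepatocytes by slow centrifugation. Their median depth in the MC38 library was 1378 UMIs and 738 genes, beside 1433 UMIs in Kupffer-like and 11429.5 UMIs in monocyte- or macrophage-like cells. Barcodes that held free RNA or part of a cell are therefore not excluded among the hepatocyte-like cells. A cluster of 86 control cells led by Car3, also a hepatocyte gene, stayed outside that class. With each library clustered on its own, the hepatocyte-like shares were 2.62% and 33.5%.

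Because hepatocyte-like cells filled part of the MC38 library, shares were also taken among the 2914 control and 6966 MC38 cells of the named immune classes. There, T-cell-like cells were at 19.1% (17.7 to 20.6) and 4.88% (4.39 to 5.41), and monocyte- or macrophage-like cells at 25.5% (24.0 to 27.2) and 54.9% (53.7 to 56.1). NK- or ILC1-like cells were at 12.3% and 3.57%, pDC-like cells at 12.9% and 2.33%, B-cell-like cells at 6.86% and 13.4%, and neutrophil-like cells at 0.446% and 3.34%. Clusters left without a name held 12.9% of the control and 5.11% of the MC38 cells; one of them joined T cell and myeloid genes (5.06% and 2.26%) and another was led by cell cycle genes (5.29% and 1.38%).

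The mitochondrial limit set several of these shares. Without it the log2 ratio of the share, MC38 over control, turned from 0.43 to −0.39 for B-cell-like cells and from 0.55 to −0.97 for Kupffer-like cells. It moved from 0.57 to 1.31 for monocyte- or macrophage-like cells, from −3.00 to −2.37 for pDC-like cells, from −2.05 to −0.88 for cDC2-like cells and from −1.04 to −0.12 for mast-cell- or basophil-like cells. The T-cell-like value was −2.50 with the limit and −2.95 without it. With a limit of 5%, the monocyte or macrophage value was 0.05, the neutrophil value 1.54 instead of 2.37 and the hepatocyte value 2.81 instead of 8.59. The mature dendritic cell value was −0.42 instead of 0.82 with each library clustered on its own. That setting gave 1.18 for Kupffer-like and 1.54 for platelet-like cells, and the limit of 5% gave −2.09 for mast-cell- or basophil-like and −0.63 for erythroid-like cells. Among named immune cells without a limit, the mast cell or basophil value was 0.43, the NK or ILC1 value −1.40 instead of −2.32, and the pDC value −1.82. There the cDC2-like class held 439 control and 316 MC38 cells, and the cDC1-like class 434 and 182. The cDC2 ratio thus lay much nearer 0 there than the −2.05 of all kept cells with the limit.

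**Figure D1:**
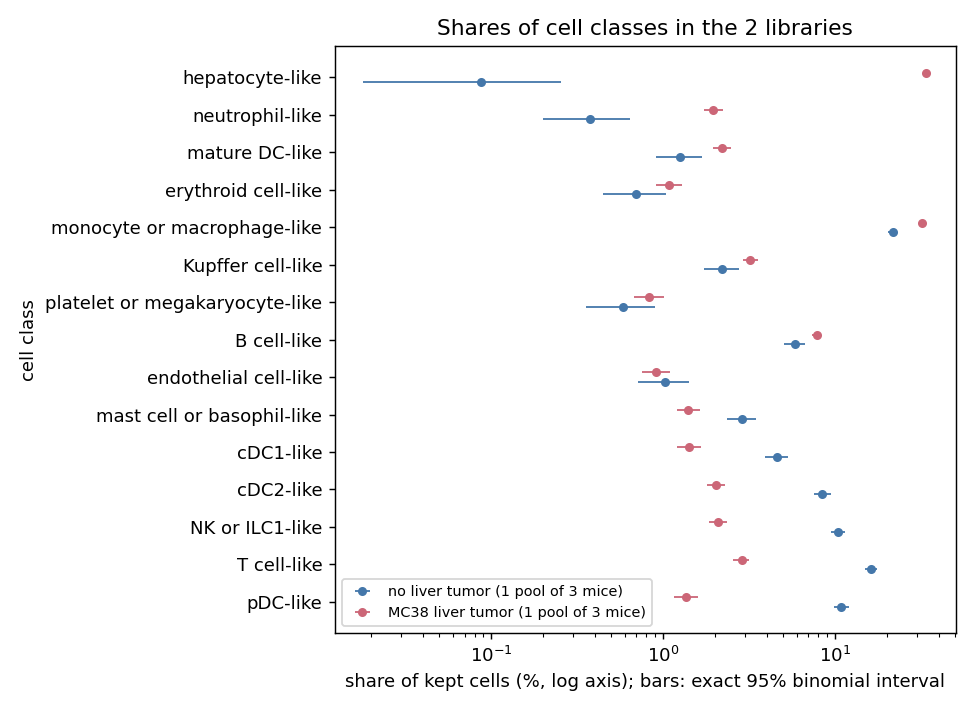
Share of kept cells (percent) in each named cell class of the library without liver tumor and the library with MC38 liver tumor; error bars are exact 95% binomial intervals that cover counting error only. T-cell-like cells stand at 16.2% and 2.86%, and hepatocyte-like cells at 0.0872% and 33.6%.

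Within the T-cell-like class, the makeup by coreceptor was compared next. Cells with a UMI of Cd8a or Cd8b1 and none of Cd4 were 26.4% (22.8 to 30.3) of 557 control cells and 30.9% (26.0 to 36.1) of 340 MC38 cells. Cells with Cd4 and neither Cd8 gene were 28.9% (25.2 to 32.9) and 28.8% (24.1 to 34.0). Cells with Foxp3, the transcription factor of regulatory T cells, were 3.05% (1.79 to 4.84) and 2.94% (1.42 to 5.34). With the mitochondrial limit of 10%, none of these differences was detectable within the class at this depth. The same genes gave 1.0% and 0.214% (Cd8), 2.5% and 0.107% (Cd4) and 0.5% and 0.107% (Foxp3) in B-cell-like cells, which should lack them. Median depths were 5931 and 4584.5 UMIs in T-cell-like cells and 3571.5 and 2774 in B-cell-like cells. After thinning to 1000 UMIs, which left out 6 control and 5 MC38 cells, the 3 shares were 18.3% and 20.6%, 8.89% and 12.8%, and 0.544% and 1.49%. With a mitochondrial limit of 30%, the Cd8 share was 22.2% (20.6 to 23.9) of 2529 control cells and 28.7% (24.8 to 32.8) of 516 MC38 cells, intervals that do not overlap, and the Foxp3 share was 1.30% (0.900 to 1.83) and 3.10% (1.78 to 4.99). The class leaves out the unnamed cluster that joined T cell and myeloid genes, with 174 control and 269 MC38 cells. Foxp3 was detected in 3.45% and 11.2% of its cells, Cd8a in 24.1% and 37.5% and Cd4 in 44.8% and 32.3%. The class shares therefore do not cover all cells with T cell genes.

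The next comparison asks how the transcripts of T-cell-like cells differed between the libraries, in CPM, the UMIs of a gene scaled to the same class total in each library. Lag3 (ENSMUSG00000030124, GRCm38 chromosome 6, 124904361 to 124911705) and Pdcd1 (ENSMUSG00000026285, chromosome 1, 94038305 to 94052553), which encode inhibitory receptors, were higher with the liver tumor. Lag3 stood at 6.48 CPM in the control and 80.5 CPM in the MC38 library, a log2 fold of 3.63 (3.01 to 4.32), and Pdcd1 at 11.1 and 88.0 CPM, a log2 fold of 2.99 (2.49 to 3.52). Of the costimulatory receptors, Tnfrsf4 (ENSMUSG00000029075, chromosome 4, 156013843 to 156016612) was at 25.4 and 199 CPM and Tnfrsf9 at 17.8 and 91.3 CPM. Zbtb16 (ENSMUSG00000066687, chromosome 9, 48654297 to 48836222), the transcription factor of innate-like T cells, was lower, at 56.5 and 8.59 CPM, a log2 fold of −2.72 (−3.55 to −1.98). Ccr2, a chemokine receptor for entry into tissue, was at 250 and 94.5 CPM.

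The other T cell genes picked by the naming rule as higher had log2 folds of 2.64 for AA467197, 1.91 for the cytokine signaling inhibitor Socs3, 1.77 for Pmepa1, 1.75 for Treml2, 1.53 for Igfbp4, 1.49 for Tnfsf8, 1.41 for the glycolytic enzyme Tpi1 and 1.37 for Serpina3g. Those picked as lower were Ckb (−2.12), Lpar6 (−1.98), Rcbtb2 (−1.87), Dtx1 (−1.54), St3gal6 (−1.48), Pde3b (−1.34), the chaperone Hsp90b1 (−1.18), Hmgb2 (−1.18) and the interferon-induced Ifit1 (−2.32), Isg15 (−1.86) and Ifi27l2a (−1.35). Among genes named in advance, Cd8a was at 109 and 197 CPM (log2 fold 0.86, 0.65 to 1.07), a gene that also leads one of the T cell clusters, and Fasl at 50.2 and 37.0 CPM (−0.44, −0.86 to −0.03). The death receptor Fas (22.7 and 16.6 CPM), Cd274 (13.2 and 14.0 CPM) and Foxp3 (9.45 and 14.0 CPM) had intervals that included no difference.

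The class joined a cluster led by Cxcr6 (387 control and 190 MC38 cells) and one led by Dapl1, Lef1 and Tcf7 (170 and 150 cells). Within the Cxcr6-led cluster the log2 folds were 4.37 (3.62 to 5.21) for Lag3, 3.14 (2.63 to 3.67) for Pdcd1, 3.18 for Tnfrsf4, 2.06 for Cd8a and −2.49 for Zbtb16. In the Dapl1-led cluster Lag3 was at 7.53 and 8.41 CPM (0.16, −1.65 to 1.88), Pdcd1 was higher with 0 and 7 UMIs (lower end of the log2 interval 1.1), and Fas had a log2 fold of −1.29 (−2.4 to −0.30). Some class differences were seen there and others were not. Isg15 (−0.04, −1.01 to 0.90), Ckb (−0.01), Rcbtb2 (−0.01), Tpi1 (0.23), Tnfsf8 (0.48), Serpina3g (7 and 12 UMIs), Tnfrsf4 (1 and 5 UMIs), Tnfrsf9 (4 and 1 UMIs), Ccr2 (0.16), Cd8a (−0.18) and Fasl (5 and 8 UMIs) showed no detectable difference, and neither did the list examples Ccl3, Ccl4, Tbx21, Ero1l, Bnip3, Bbc3, Tnfrsf1a, Cd40lg, Xcl1, Cxcr6 and Cd101; Zbtb16 and Klrg1 had 2 and 0 UMIs each. Genes that did differ there were AA467197 (0 and 24 UMIs), Socs3 (2.08), Pmepa1 (1.61), Treml2 (1.49), Tnfrsf18 (1.42) and Igfbp4 (1.13), which were higher, and Ifit1 (20 and 3 UMIs), Hmgb2 (−1.36), Lpar6 (−1.23), St3gal6 (−1.08), Cd28 (−0.95), Dtx1 (−0.81), Ifi27l2a (−0.71), Pde3b (−0.61) and Hsp90b1 (−0.55), which were lower. In the Cxcr6-led cluster Fasl showed no detectable difference (−0.37, −0.81 to 0.06). With a mitochondrial limit of 30%, Lag3 had a log2 fold of 4.49, Pdcd1 3.89, AA467197 3.35, Foxp3 1.95, Hsp90b1 −0.50, Ifit1 −0.19, Fas 0.09 and Cd274 −0.60; with at least 500 genes per cell, Ifit1 was at 0.22 and Isg15 at −1.06. Markers of other cell types in the T-cell-like class were also higher in the MC38 library, with hepatocyte markers at 145 and 575 CPM and erythroid markers at 23.5 and 2110 CPM, while plasma cell markers were at 641 and 87.5 CPM.

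Checkpoint receptor genes were higher as a list in T-cell-like cells. Their median log2 fold was 0.91 (0.53 to 1.24), or 0.50 over members with at least 100 UMIs, at percentile 100.0 of 10000 random lists matched on expression, and 7 of 11 measured members, among them Lag3, Pdcd1, Havcr2 and Ctla4, were at least 1.5 times higher and none lower. Glycolysis and hypoxia genes had a median of 0.65 (0.57 to 0.76, percentile 100.0), with 9 of 14 members higher, such as Tpi1 and Bnip3 (2.58), and Ero1l lower (−0.76). The cytotoxic list had a median of 0.28 (percentile 99.9), with Ccl3 at 5.94 and 96.6 CPM, Ccl4 at 27.3 and 171 CPM and Ifng, Cst7 and Prf1 among its 5 higher members of 16, and Klrg1 (−2.06) and Tbx21 (−0.69) lower. Few cells held these chemokine UMIs, with Ccl3 detected in 2.51% of control and 5.88% of MC38 cells and Ccl4 in 4.67% and 7.06%. Within the Cxcr6-led cluster Ifng was at 81.5 and 270 CPM but was detected in 26.1% and 17.4% of cells. Naive and central memory genes had a median of 0.30 (percentile 99.8), with Igfbp4 higher. Regulatory T cell genes had a median of 0.28 (−0.05 to 0.57, percentile 97.7), an interval that included no difference, with Tnfrsf4, Tnfrsf18 (1.02) and Ctla4 higher and Klrg1 lower.

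Type I interferon response genes were lower in T-cell-like cells, with a median of −1.20 (−1.46 to −0.84, percentile 0.0) and 10 of 16 members lower. Tissue residence genes had a median of −0.49 (−0.78 to −0.24, percentile 0.0), with Xcl1 (−0.90), Cxcr3, Itga1 and Cxcr6 lower and Cd101 (1.67) higher; Cxcr6 also leads one of the clusters. Activation and costimulation genes had a median of −0.14 (percentile 18.0), with Tnfrsf4, Tnfrsf9 and Tnfrsf18 higher and Cd40lg (−1.71) and Cd28 (−0.60) lower. Apoptosis and death receptor genes had a median of −0.01 (−0.17 to 0.16, percentile 52.5), with Bbc3 (0.96) higher and Tnfrsf1a (−1.23) lower. Cell cycle genes were at −0.09 (percentile 22.3), MHC class I genes at −0.18 (3.8), MHC class II genes at −0.21 (8.9), interferon gamma response genes at −0.28 (0.5), immediate-early genes at −0.21 (2.6) and mitochondrial genes at −0.29 (0.5).

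Some T cell list medians depended on the cells kept. The type I interferon median was −0.54 with at least 500 genes per cell and −0.64 with a mitochondrial limit of 30%. The cytotoxic median was −0.14 when each cell weighed the same, where Xcl1 was at −1.57 and the MHC class II median at 0.25. Apoptosis genes were at 0.08 with either change of limit. With the limit of 30%, Ccl4 was at 3.62 instead of 2.65 and Klrg1 at −1.02. The regulatory list was at −0.05 with at least 500 genes per cell and 1.46 with the limit of 30%, and at 0.99 over members with at least 100 UMIs. With the limit of 30% the cell cycle list was at 0.76 and the MHC class II list at 1.06.

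In the monocyte- or macrophage-like class, Arg1 (ENSMUSG00000019987, chromosome 10, 24915221 to 24927484), which encodes the arginine-degrading enzyme of immunoregulatory macrophages, stood at 2.41 CPM in the control and 454 CPM in the MC38 library. That is a log2 fold of 7.56 (6.88 to 8.34) for Arg1. Of its 20786 MC38 UMIs, 8822 came from the 72 cells of a Saa3-led cluster, without which the Arg1 values were 2.41 and 270 CPM. The complement subunit gene C1qb (ENSMUSG00000036905, chromosome 4, 136880129 to 136886187) was at 39.2 and 550 CPM (3.81, 3.64 to 3.99) and the complement receptor gene C3ar1 at 3.11 and 101 CPM (5.01, 4.41 to 5.69). Lrg1 (7.32) and the decoy cytokine receptor Il1r2 (5.43) were higher as well. Interferon-induced genes were lower, with Ifit3 (ENSMUSG00000074896, chromosome 19, 34583531 to 34588731) at 83.6 and 4.87 CPM (−4.10, −4.33 to −3.88), Rsad2 at −3.62, Pydc4 at −3.46 and Mx1 at −3.19; Eno3 (−3.42) and Marcksl1 (−3.01) were the other lower genes that lead no cluster of the class.

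Different clusters held this class in the 2 libraries, so the class values mix makeup with expression. Of 744 control cells, 574 were in a cluster led by Ace, a gene of nonclassical monocytes, and 145 in one led by Cxcl10. Of 3824 MC38 cells, 1927 were in a cluster led by the classical monocyte genes Chil3, F13a1 and Vcan, 1011 in one led by F11r, 580 in one led by Cd14 and Spp1, 182 in the Cxcl10-led one and 72 in one led by Saa3. The rule also picked genes that lead these clusters, namely Dab2, Spint1, Htra3, Spink2, Spp1, Saa3 and F11r as higher and Ace, Serpinb10, Ifit1, Ifit2, Isg15 and Cxcl10 as lower, and their class values are not read as differences here. Arg1, C1qb and Eno3 are among the fixed markers that named the class, which the within-cluster values below bear on. The Cxcl10-led cluster used there was formed from these same data, and its cells may differ in makeup too. Control and MC38 values within it were 1140 and 5600 CPM for Chil3, 48.4 and 26.7 for Ace and 94.7 and 14.9 for Nr4a1. Eno3, given below, showed no detectable difference there.

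Within the Cxcl10-led cluster, which both libraries filled, Arg1 was at 3.46 and 167 CPM (log2 fold 5.59, 4.36 to 7.22), C1qb at 34.6 and 903 CPM (4.71, 4.30 to 5.14) and C3ar1 at 4.84 and 109 CPM (4.49, 3.43 to 5.82). Spint1 (4.40), F11r (3.69), Saa3 (2.31) and Spp1 (0.88, 0.42 to 1.36), which lead other clusters, were also higher there. Ifit3 was at 341 and 67.4 CPM (−2.34, −2.61 to −2.07), Mx1 at −2.22, Marcksl1 at −1.91 and Rsad2 at −1.50, while Eno3 showed no detectable difference (0.06, −0.96 to 1.13). Fas was at 42.3 and 14.9 CPM over the class (−1.50, −1.70 to −1.30) and 91.9 and 37.2 CPM within that cluster (−1.31). Cd274, the gene of a checkpoint ligand, was at 26.3 and 14.0 CPM over the class (−0.91, −1.15 to −0.67) and 75.3 and 62.6 CPM within the cluster (−0.27, −0.64 to 0.11). Over the class, Ccr2 was at 1120 and 1370 CPM, Itgam at 232 and 314 CPM and Adgre1 at 136 and 121 CPM. With a mitochondrial limit of 30% Arg1 had a log2 fold of 6.91 over the class, with called doublets kept Lrg1 had 6.50, and with at least 500 genes per cell Rsad2 had −4.35.

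Among lists in the monocyte- or macrophage-like class, complement genes had a median log2 fold of 1.62 (1.49 to 1.77, percentile 100.0), with 6 of 10 higher and Cfb (−1.24) and Cd55 (−1.20) lower. C1qa, C1qb and C1qc among the higher members are fixed markers of the class. Cell cycle genes followed at 1.41 (1.11 to 1.89, percentile 100.0), with 14 of 18 higher, such as Stmn1 (2.96) and Ccnb2 (2.99). Clusters led by cell cycle genes were left unnamed by rule, which took 5.29% of the control and 1.38% of the MC38 cells out of all classes, so the cell cycle values here and in the other classes cover only the cells left and do not show which library held more cycling cells. Glycolysis and hypoxia genes were at 1.11 (1.02 to 1.17, percentile 100.0), with 13 of 15 higher, among them Vegfa (3.33) and Bnip3 (1.84). The tumor-associated macrophage list was at 0.70 (0.62 to 0.87, percentile 100.0), with 11 of 19 members higher, including Arg1, Stab1, Gpnmb and Nos2, and Il1rn (−1.06), Cd274, Pdcd1lg2 and Siglec1 lower. Of the higher members, Spp1, Chil3 and Trem2 lead clusters filled mostly by MC38 cells, so this median also mixes makeup with expression. Arg1, Mrc1, Trem2, Gpnmb and Chil3 are also fixed markers of the class. Within the Cxcl10-led cluster Trem2 was at 43.6 and 234 CPM. Hmox1, counted as higher over the class, was at 98.2 and 74.0 CPM there. Lysosome and phagocytosis genes were at 0.47 (percentile 100.0), with the engulfment receptor Mertk (2 control and 763 MC38 UMIs, a log2 fold of 5.88, 4.02 to 8.93) and Ctsl (2.63) among 6 of 15 higher.

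On the lower side, each of the 16 type I interferon response genes was at least 1.5 times lower in this class, with a median of −3.07 (−3.15 to −2.86, percentile 0.0). Ifit1, Ifit2 and Isg15 among them lead the Cxcl10-led cluster, which held a larger part of the control than of the MC38 cells of the class. The count and the median therefore mix makeup with expression. Within that cluster Ifit3, Mx1 and Rsad2 were also lower, by less than over the class. Interferon-induced genes lead that cluster, so it gathers cells high in them from both libraries. The smaller folds inside it therefore do not show how much of the class values is makeup. Interferon gamma response genes were at −1.12 (−1.22 to −1.01, percentile 0.0), with 13 of 19 lower, such as Tgtp2 (−2.47). Cxcl10, Cxcl9 and Gbp5, which lead the same cluster, are among the lower members, so the same limit holds for this list. MHC class II genes were at −0.79 (−0.82 to −0.74, percentile 0.1), with H2-Eb1 at 914 and 489 CPM, H2-Aa at 1300 and 718 CPM and 5 of 9 lower. Within the Cxcl10-led cluster H2-Eb1 was at −0.43 (−0.51 to −0.34) and H2-Aa at −0.21 (−0.28 to −0.13), nearer 0 than over the class, and H2-DMa was higher (0.66, 0.52 to 0.80). MHC class I genes were at −0.75 (percentile 0.0), with H2-Q7 (−2.08) and H2-T23 (−1.69) among 9 of 14 lower. Immediate-early genes were at −0.74 (percentile 0.0), with Hspa1b (−2.37) among 10 of 17 lower and Egr1 (0.91) higher. Inflammatory cytokine and costimulation genes were at −0.52 (percentile 0.7), with Cd40 (−2.19) and Tnfaip3 (−1.98) lower and Il1a (1.75) and Cd80 (0.99) higher. Apoptosis genes were at −0.43 (percentile 0.2), with Tnfsf10 (−2.85) and Bcl2 (−1.69) lower and Bcl2l1 (1.66) higher.

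Chemokine genes went both ways in this class, with a median of 0.03 (percentile 52.7), 5 of 17 higher, such as Ccl7 (3.25) and Ccl24 (1.61), and 6 lower, such as Ccl5 (−1.82). Iron and heme handling genes were at 0.10 (percentile 65.5), with the ferritin gene Fth1 at 3120 and 6920 CPM and Hpgd lower (−1.97). The mitochondrial list was at −0.45 (percentile 0.2), with mt-Nd3 at −1.19 and mt-Co3 at −0.14, and the median mitochondrial share of a cell was 6.52% and 5.04%. Cells were kept by a limit on mitochondrial UMIs, which took out a larger part of the control barcodes. The mitochondrial values here and in the other classes therefore cover only the cells left and do not compare the whole libraries. Neutrophil markers in the class were at 229 and 6050 CPM, and Mmp8, one of them, is a leading gene of the Chil3-led cluster. Hepatocyte markers in the class were at 113 and 340 CPM. In the Cxcl10-led cluster several of these list examples did not keep the direction of the class. Ccl24 was lower there (74.7 and 14.4 CPM, −2.37, −2.98 to −1.80) and Cd55 higher (1 and 11 UMIs, 2.80, 0.02 to 8.23). Cfb (0.19, −0.38 to 0.78), Ccnb2 (4 and 3 UMIs, −1.07, −3.85 to 1.49), Egr1 (−0.28, −0.90 to 0.35), Cd80 (−0.38, −1.49 to 0.75), Ccl7 (1.66, −1.50 to 7.23) and Bcl2 (−0.40, −0.93 to 0.13) showed no detectable difference there. With called doublets kept, H2-Eb1 was at −1.72 and H2-Aa at −1.73 and Cd55 was at 0.09. The complement median was 2.59 over members with at least 100 UMIs, Stmn1 was at 1.87 with at least 500 genes per cell, and Vegfa was at 3.92 when each cell weighed the same. With a mitochondrial limit of 30%, Mertk was at 4.42, Ccl7 at 3.98, Il1a at 1.04 and the iron list at −0.12; the chemokine list was at −0.01 with each cell weighing the same.

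**Figure D2:**
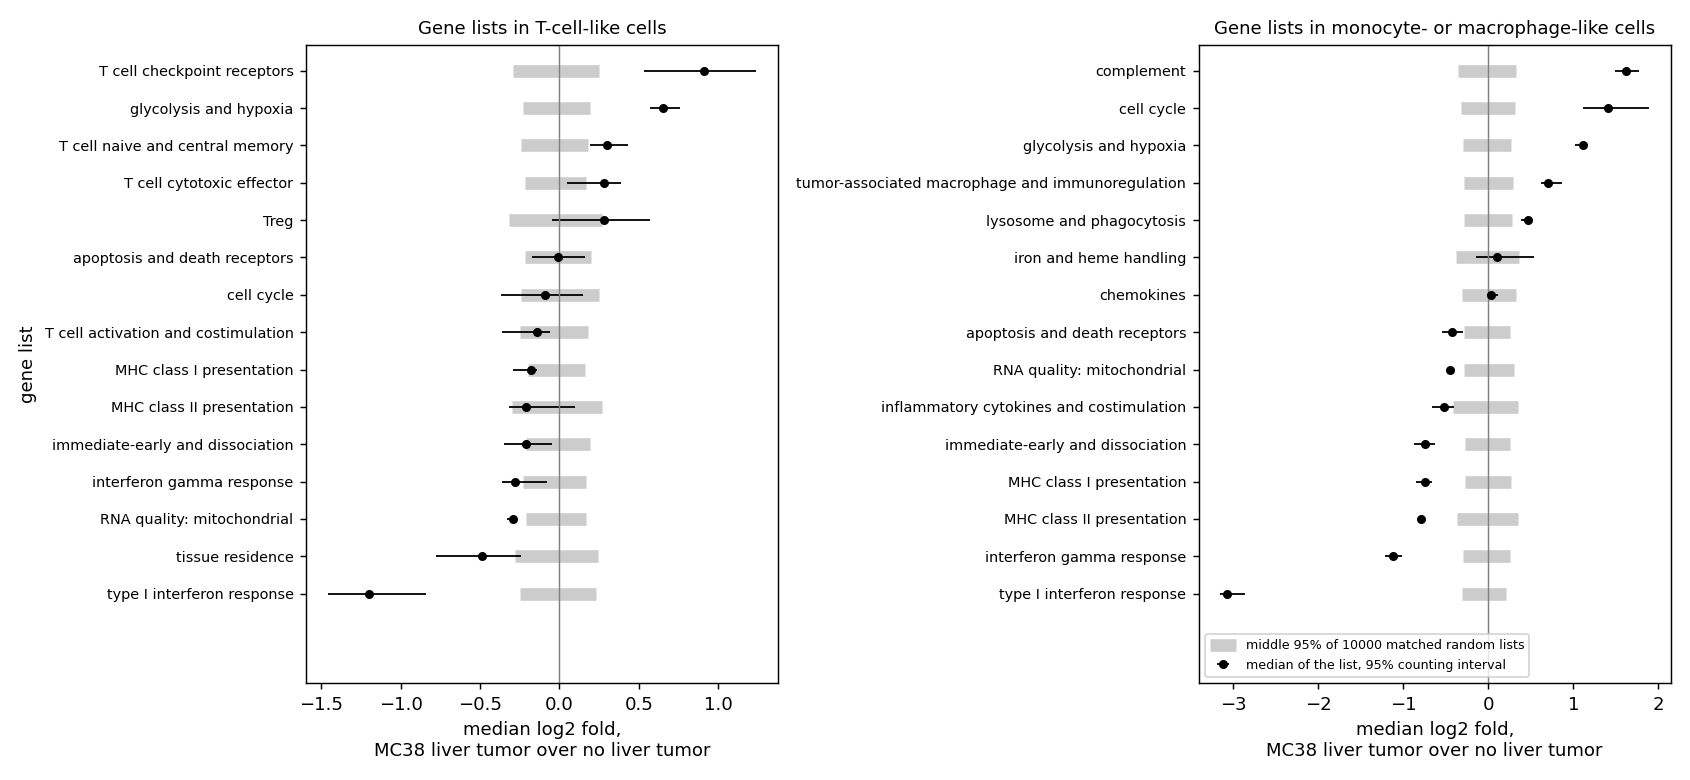
Median log2 fold (MC38 liver tumor over no liver tumor) of each fixed gene list in T-cell-like cells and in monocyte- or macrophage-like cells; points are medians with 95% counting intervals, and grey bars are the middle 95% of 10000 random lists matched on expression. The type I interferon response stands at −1.20 and −3.07, and checkpoint receptors in T-cell-like cells at 0.91. Ifit1, Ifit2 and Isg15 of the interferon list lead a monocyte- or macrophage-like cluster, so its value in that class mixes makeup with expression. The tumor-associated macrophage list in that class and the naive and tissue residence lists in T-cell-like cells also hold genes that lead clusters.

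**Figure D3:**
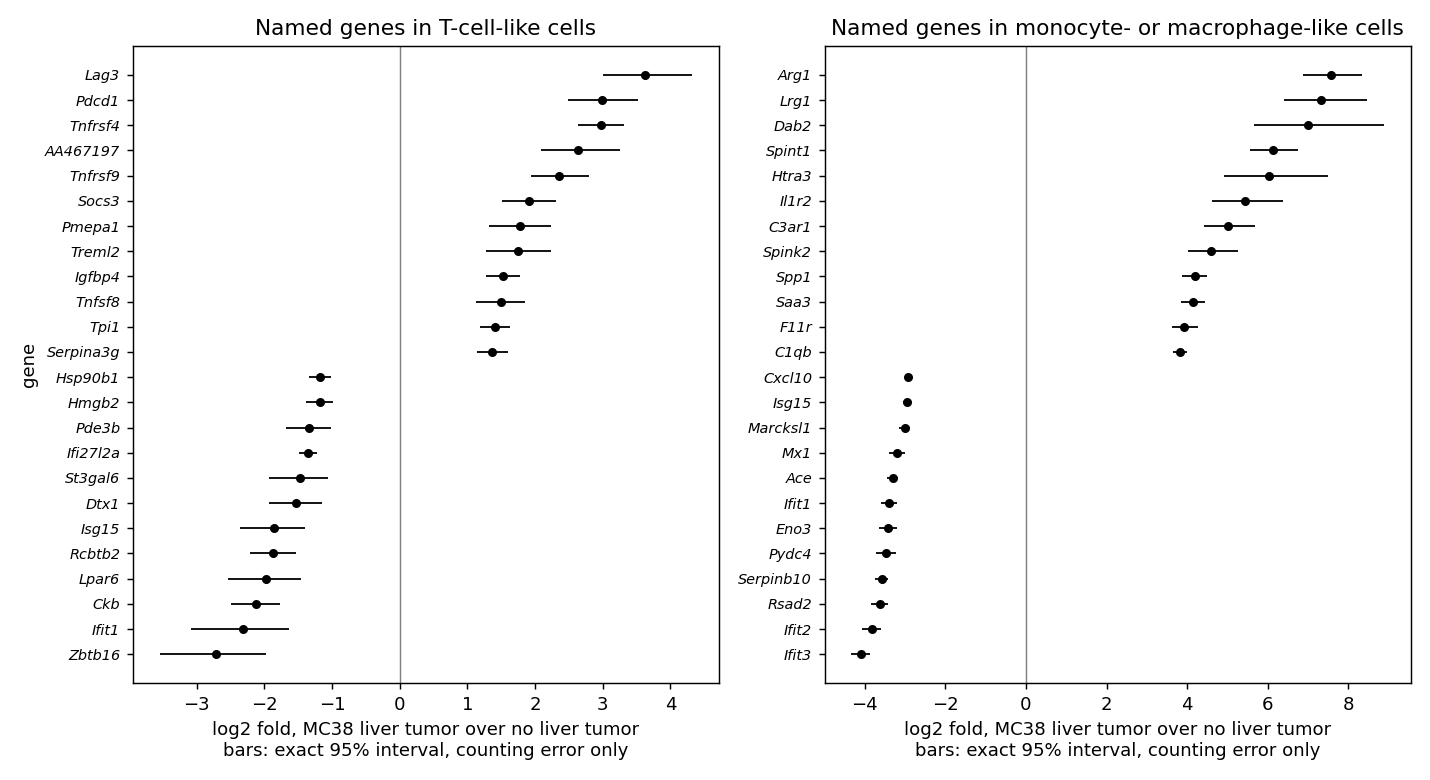
Log2 fold (MC38 liver tumor over no liver tumor) of the genes picked by the naming rule in T-cell-like cells and in monocyte- or macrophage-like cells, with exact 95% intervals that cover counting error only. In T-cell-like cells Lag3 stands at 3.63 and Zbtb16 at −2.72, and in monocyte- or macrophage-like cells Arg1 stands at 7.56 and Ifit3 at −4.10; Dab2, Spint1, Htra3, Spink2, Spp1, Saa3, F11r, Ace, Serpinb10, Ifit1, Ifit2, Isg15 and Cxcl10 lead clusters of that class.

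Lower type I interferon response genes were seen in each of the 7 classes compared. The median log2 fold was −1.04 in NK- or ILC1-like cells (8 of 14 members lower), −0.88 in B-cell-like cells (7 of 13), −1.75 in cDC1-like cells (9 of 13), −1.43 in cDC2-like cells (11 of 16) and −1.53 in pDC-like cells (10 of 16), beside the T cell and monocyte or macrophage values. Each was at percentile 0.0, and no member was at least 1.5 times higher in any of these classes. Ifi27l2a was at 74.7 and 13.9 CPM in NK- or ILC1-like cells, 687 and 181 CPM in cDC2-like cells and 819 and 272 CPM in pDC-like cells, where Ifi44 was at 56.5 and 8.79 CPM. Over members with at least 100 UMIs, the median was −0.62 in cDC1-like and −0.81 in cDC2-like cells. With each cell weighing the same it was −0.77 in cDC1-like cells, and Ifi27l2a in NK- or ILC1-like cells had a log2 fold of −1.43 instead of −2.43 with at least 500 genes per cell. Heat shock genes of the immediate-early list were lower too, such as Hspa1b in T-cell-like (40.0 and 12.3 CPM) and pDC-like cells (127 and 2 UMIs), and Hspa1a in NK- or ILC1-like cells (42 and 0 UMIs). In T-cell-like MC38 cells Hspa1b was detected in 0.294% of 340 cells, so its 23 UMIs lay in 1 cell. The T cell value of Hspa1b was −1.70, and −4.42 with a mitochondrial limit of 30%. Hepatocyte markers were higher in each of these 7 classes, for example at 95 and 502 CPM in pDC-like cells.

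In cDC1-like cells (158 and 169 cells), Plet1 had 1 control and 606 MC38 UMIs, a log2 fold of 9.30 (6.82 to 14.61), and in cDC2-like cells (290 and 242 cells) 2 and 541 UMIs (8.29, 6.43 to 11.34). Ccl17, a T-cell-attracting chemokine, was at 13.5 and 356 CPM in cDC1-like and 23 and 633 CPM in cDC2-like cells. Ifitm1 (30.7 and 2750 CPM) and Htra3 (0.958 and 50.7 CPM) were higher in cDC2-like cells, and Ppp1r14a (2.91) and Sult1a1 (2.39) in cDC1-like cells. Cd274 was at 6.21 and 14.1 CPM in cDC1-like and 7.99 and 27.4 CPM in cDC2-like cells, and Il1b had log2 folds of 2.77 and 1.86. Lower genes were Serpinb10 (−3.89), Hspa1b (−2.90) and Hspa1a (−2.85) in cDC1-like cells and Hspa1b (−4.24), Hpgd (−3.08) and Hspa1a (−2.88) in cDC2-like cells. With a mitochondrial limit of 30%, Ccl17 had log2 folds of 2.98 instead of 4.72 in cDC1-like and 2.09 instead of 4.78 in cDC2-like cells, Il1b 1.81 in cDC1-like cells and Htra3 4.78 instead of 5.73 in cDC2-like cells. With each cell weighing the same, Plet1 had 9.91 and 9.37, and Ppp1r14a 1.68 and Cd274 1.84 in cDC1-like cells.

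The tumor-associated macrophage list was higher in both dendritic classes, at 0.60 in cDC1-like cells (6 of 11 higher, led by Chil3 at 7.37) and 1.38 in cDC2-like cells (9 of 15 higher, with Arg1 at 4.59), each at percentile 100.0. Arg1 in cDC2-like cells was at 1.60 and 38.5 CPM beside 1.28 and 31.8 CPM of the hepatocyte gene Orm1. Hepatocyte-like MC38 cells held 2990 CPM of Arg1 and 3240 CPM of Orm1, so free hepatocyte RNA is not excluded as the source of Arg1 there. Markers of other cell types were higher too, with neutrophil markers at 14.1 and 133 CPM in cDC1-like and 24 and 102 CPM in cDC2-like cells, epithelial markers at 13.5 and 57.6 and at 25.6 and 162 CPM, and stellate markers at 4.51 and 21.8 and at 6.71 and 23.7 CPM. Chil3 leads the largest MC38 monocyte cluster, so RNA carried over from other cells is not excluded for this list or for the complement list. Complement genes were at 1.87 and 1.63 (percentile 100.0 each), glycolysis genes at 0.38 and 0.70 (100.0 each), lysosome genes at 0.47 (100.0) and 0.15 (95.2), and chemokine genes at 0.97 (100.0) and −0.16 (15.5). Interferon gamma response genes were at −0.11 (percentile 34.1) in cDC1-like cells and 0.80 (100.0) in cDC2-like cells, where Cxcl9 (33.9 and 134 CPM) was among 9 of 18 higher. Inflammatory genes were at −0.50 (1.5) and 0.30, immediate-early genes at −0.45 and −0.56 (0.0 each), and iron genes at −0.35 (4.2) and −0.17 (16), although Fth1 was higher (1.26 and 1.01). MHC class II genes were at 0.00 (52.6) and 0.15 (91.7), MHC class I at −0.25 (1.8) and −0.09 (22.9), apoptosis genes at −0.12 (30.6) and 0.17 (94.9), cell cycle genes at 0.03 (72.6) and 0.14 (85.9), and mitochondrial genes at −0.44 (0.0) and −0.43 (0.1).

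Several of these dendritic cell medians were sensitive. The cDC1 complement median was −0.02 with a mitochondrial limit of 30%, where C1qb was at −0.28 instead of 2.76, and 0.94 with called doublets kept. In cDC1-like cells the tumor-associated macrophage median was 2.18 when each cell weighed the same, the iron median 1.05 over members with at least 100 UMIs, and the chemokine median 1.65 with every detected member. Chil3 was at 8.99 with at least 500 genes per cell, and the small apoptosis and cell cycle medians turned to 0.01 with the limit of 30% and −0.08 with at least 500 genes. In cDC2-like cells the tumor-associated macrophage median was 0.30 and the complement median 0.79 over members with at least 100 UMIs, and the chemokine median 0.95 with every detected member; over members with at least 100 UMIs the iron, lysosome and cell cycle medians turned to 0.23, −0.04 and −0.13, and Cxcl9 was at 1.26 instead of 1.98 with at least 500 genes per cell.

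In pDC-like cells (375 control and 162 MC38 cells), the stress-response gene Fkbp5 was at 16.9 and 54.3 CPM, Socs3 at 18.8 and 57.5 CPM and Slpi at 128 and 310 CPM. Myadm was lower, at 50.4 and 11.2 CPM, and Cd8a was at 70.5 and 178 CPM (log2 fold 1.34, 1.06 to 1.61). Arg1 had 5 control and 51 MC38 UMIs (4.68, 3.36 to 6.36), which is 1.59 and 40.7 CPM, beside 0.957 and 41.5 CPM of the hepatocyte gene Orm1. Arg1 is also a hepatocyte gene, so free hepatocyte RNA is not excluded as the source here. T cell markers were at 523 and 758 CPM in the class (0.54, 0.42 to 0.65) and neutrophil markers at 9.57 and 87.1 CPM, so RNA carried over from other cells is not excluded for Cd8a or the next lists. The tumor-associated macrophage list, which holds Arg1, was at 0.39 (percentile 98.8). Complement genes were at 0.92 (99.9), glycolysis genes at 0.29 (99.7), inflammatory genes at −1.02 (0.3), with Tnfaip3 at −1.44, chemokine genes at −0.60 (1.9), with Ccl4 at −1.75, immediate-early genes at −0.52 (0.0) and mitochondrial genes at −0.24 (0.8). The remaining lists lay between percentiles 17.7 and 83.9: cell cycle (−0.19), MHC class I (−0.07) and II (0.10), interferon gamma (−0.06), apoptosis (−0.10), iron (0.11) and lysosome (0.05). With called doublets kept, the chemokine median was 0.19, the inflammatory 0.30, the complement 2.37 and the macrophage list 1.68, and over members with at least 100 UMIs the macrophage list was at −0.04 and the lysosome list at −0.02. With a mitochondrial limit of 30%, Ccl4 was at −0.69 and the cell cycle list at 0.05, and with at least 500 genes per cell the inflammatory list was at −0.27.

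In NK- or ILC1-like cells, Pmepa1, a target of TGF-beta signaling, was at 6.13 and 57.1 CPM, C1qtnf6 at 18.4 and 60.4 CPM and the proapoptotic gene Bcl2l11 at 84.1 and 200 CPM. Lower genes were Zeb2, a transcription factor of NK cell maturation, at 411 and 169 CPM, Lpar6 at 53.5 and 18.0 CPM and Asb2 at 72.4 and 26.9 CPM. Pdcd1 was at 6.13 and 40.8 CPM (log2 fold 2.73, 1.77 to 3.83) and Fasl at 104 and 135 CPM (0.39, 0.08 to 0.70). A Klra8-led cluster held 248 control and 163 MC38 cells of the class, and a Gzmb-led one 111 and 86. Glycolysis genes had a median of 0.55 (percentile 100.0), regulatory T cell genes 0.37 (97.8), immediate-early genes −0.60 (0.0), interferon gamma genes −0.41 (0.2), mitochondrial genes −0.37 (0.1) and tissue residence genes −0.35 (2.2). Checkpoint (0.01), cytotoxic (−0.04), activation (0.01), naive (−0.07), MHC class I (−0.08) and II (−0.03), apoptosis (−0.18) and cell cycle genes (−0.03) lay between percentiles 15.9 and 74.8, and turned direction with at least one setting except for MHC class I and apoptosis genes. The cell cycle median was 0.72 with a mitochondrial limit of 30%, where Pmepa1 was at 2.52 instead of 3.22 and Pdcd1 at 3.42, and the MHC class II median was 0.33 with called doublets kept.

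In B-cell-like cells (200 and 934 cells), Serpina3g was at 25.4 and 156 CPM, Pik3ip1, an inhibitor of a growth signaling kinase, at 35.6 and 162 CPM and Ppp1r21 at 16.9 and 88.2 CPM. The chaperone Hsp90b1 was at 2240 and 293 CPM, Eaf2 at 159 and 13.1 CPM and Hspa1b at 73.7 and 2.44 CPM, while plasma cell markers in the class were at 15200 and 947 CPM. Interferon gamma response genes were higher, at 0.59 (percentile 99.7), with 7 of 15 members higher, among them Iigp1 with 0 control and 49 MC38 UMIs. MHC class II genes were at 0.53 (99.6), with H2-Oa at 118 and 287 CPM. B cell activation genes were at −0.38 (0.1), with Irf4 (−1.29) lower and Cd83 (1.41) higher, immediate-early genes at −0.37 (0.0) and apoptosis genes at −0.27 (0.5), with Bcl2 (0.91) higher. Cell cycle (0.14), glycolysis (0.02), MHC class I (−0.02) and mitochondrial genes (0.02) lay between percentiles 9.8 and 34.5. With called doublets kept, Hsp90b1 was at −0.48 instead of −2.93, Eaf2 at 0.01 instead of −3.60 and Cd83 at 0.79; with a mitochondrial limit of 30%, Hspa1b was at −2.39, Serpina3g at 1.75, Pik3ip1 at 1.51, Ppp1r21 at 1.51 and H2-Oa at 0.46. B cell activation was at 0.06 over members with at least 100 UMIs. The small B cell medians turned too, to −0.21 for cell cycle with called doublets kept, −0.48 for mitochondrial and 0.01 for MHC class I genes with the limit of 30%, and −0.06 for glycolysis with at least 500 genes per cell.

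Over all kept cells, where makeup and expression are mixed, the genes highest in the MC38 library were mostly transcripts of hepatocytes, such as the metallothionein genes Mt1 (36.0 and 1660 CPM) and Mt2 (5.06 and 356 CPM), the acute phase gene Orm1 (5.26 and 332 CPM), the iron hormone gene Hamp (2.71 and 166 CPM), Fam25c (1.85 and 203 CPM), Serpina1e, Slc25a47 and Nnmt. Hepatocyte-like cells held 105233 of the 134326 MC38 UMIs of Mt1. Lrg1 and Arg1 (10.2 and 583 CPM) were the others, and Arg1 stood at 2990 CPM in hepatocyte-like MC38 cells as well. The genes lowest in the MC38 library mark the classes with smaller shares: Cd209a (144 and 11.2 CPM) and Cd209d of dendritic cells, Siglech (305 and 43.8 CPM), Cox6a2 and Ccr9 of pDCs, Klre1 and Ncr1 of NK cells, and Cxcr6, Cd28 and Cxcr3 of lymphocytes. Cd209a was detected in 17.4% of control and 1.92% of MC38 cells. It was also lower within the unnamed cluster with T cell and myeloid markers (324 and 1.55 CPM). Its difference is therefore not read as the dendritic share alone. The median gene lay at a log2 shift of −0.15 between the libraries. With a mean over cells, Arg1 had a log2 fold of 4.72 instead of 5.84, and with a mitochondrial limit of 30% Hamp had 5.29 instead of 5.93 and Cxcr6 −3.29 instead of −2.69.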

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

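Of the tests in this part, the chance pairing of T cells with myeloid cells was written down before its value was seen; the other 5 tests and the 3 stricter pair definitions were chosen after the results were seen.

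A signal in cells outside the comparisons was an unnamed cluster led by Tnnt2, Hmga2, Bgn and Krt14, with 1.47% (1.26 to 1.70) of the MC38 cells (175 cells against 2 in the control) and Ptprc, the common leukocyte gene, at 44.7 CPM against 677 CPM in immune cells. A second signal, in genes outside the lists compared, was cells with at least 10 UMIs of the granule genes Mpo, Elane, Prtn3, Ctsg and Ms4a3, which were 2.23% (1.97 to 2.51) of the MC38 cells and 0.436% (0.244 to 0.718) of the control cells; 182 of these 265 MC38 cells lay in the Chil3-led monocyte cluster. This difference rested on Prtn3: without it, the shares with at least 10 UMIs were 0.286% (0.198 to 0.399) and 0.32% (0.16 to 0.571), a count made after the first values were seen.

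The smaller share of T-cell-like cells was weighed against the mitochondrial limit and against hepatocytes filling the library. Among named immune cells the log2 ratio of the T cell share was −1.97 (−2.17 to −1.77), and it was −2.4 (−2.53 to −2.26) among named immune cells with no mitochondrial limit. Both lie below the −1 written for a pattern with another source, so neither explanation covers the pattern on its own. These shares leave out the unnamed cluster with T cell and myeloid markers. With doublet calls kept, barcodes with at least 10 UMIs of T cell markers, with or without myeloid markers, were also compared. They were 30.5% (29.0 to 32.0) of 3565 control and 7.43% (6.99 to 7.9) of 13010 MC38 barcodes. The liver tumor may be the source, but the yield of the isolation and the removal of the spleen in the MC38 group were not tested. Whether the control mice kept their spleens is not given, and 1 pool per group leaves each of these open.

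Barcodes with T cell and myeloid markers together were weighed against chance pairing in droplets, by comparing pairs with myeloid cells per T cell to those per B cell among barcodes past the gene and mitochondrial limits with doublet calls kept. The ratio was 4.08 (3.55 to 4.70) in the MC38 library and 1.48 (1.17 to 1.92) in the control, and the stricter definitions gave 3.83, 4.14 and 4.31 in the MC38 library and 1.34, 1.4 and 1.34 in the control. Chance pairing alone does not account for the MC38 pairs. The range of 0.5 to 2 for chance pairing was written for the MC38 library only. The control values lay inside it, but the interval of the 1.48 excluded equal pairing, so chance pairing is not settled for the control. The median UMI count of the cluster was 1.0 times the sum of the medians of T-cell-like and monocyte- or macrophage-like cells, which fits RNA of 2 cells under 1 barcode. Whether such cells could have been joined in the liver or during isolation was not tested.

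Hepatocyte and metallothionein transcripts, higher in each of the 7 classes compared in the MC38 library, were weighed against free hepatocyte RNA by the Mt1 to Orm1 ratio of a class over that of hepatocyte-like cells. The median over T, B, NK or ILC1 and pDC classes was 1.02 (range 0.963 to 1.21), which fits free RNA there. In monocyte- or macrophage-like cells it was 2.03 (1.93 to 2.14), so free RNA does not account for all their Mt1 and their own expression may add to it. In cDC1-like cells it was 1.81 (1.42 to 2.32) and in cDC2-like cells 2.31 (1.85 to 2.92), for which no prediction was written.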

How the results depend on the processing

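The mitochondrial limits of 30% and none, and the shares among named immune cells, were chosen after seeing the data; the other alternatives were planned. No paired analysis was possible because the labels match no mouse of one group to a mouse of the other. Values are log2 ratios or folds, MC38 over control, and where a value left its interval or turned, the cause was not tested.

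Of shares, resolution 2.0 left all 15 inside their intervals. With called doublets kept, the B-cell-like share was at 0.67 and the monocyte or macrophage share at 0.39; with at least 500 genes per cell the B share was at 0.68. A mitochondrial limit of 5% gave −2.56 for NK or ILC1, 0.05 for monocytes or macrophages and 1.54 for neutrophils. Clustering each library on its own gave 0.46 for monocytes or macrophages and −0.42 for mature dendritic cells. Thinning to 1000 UMIs gave −1.93 for T cells, 0.71 for monocytes or macrophages, 0.53 for the Cd4 subset and 1.46 for the Foxp3 subset. The limit of 30% gave −0.24 for B cells, −3.05 for T cells, 0.98 for monocytes or macrophages and 1.2 for the Foxp3 subset. No limit gave −0.39 for B cells, −0.97 for Kupffer cells, −1.95 for NK or ILC1, −2.95 for T cells, 1.31 for monocytes or macrophages and −2.37 for pDCs. Among named immune cells the values were 0.97 for B cells, −1.78 for NK or ILC1, −1.97 for T cells, 1.10 for monocytes or macrophages and −2.47 for pDCs, and with no limit as well they were 0.16 for B cells, −0.42 for Kupffer cells, −1.40 for NK or ILC1, 0.43 for mast cells or basophils, 1.86 for monocytes or macrophages and −1.82 for pDCs.

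Of gene lists, scaling by the median ratio gave −0.73 for MHC class II and 1.17 for glycolysis in monocyte- or macrophage-like cells and left 93 of 100 inside their intervals. The mean over cells gave −0.14 for the cytotoxic and 0.51 for the naive list in T-cell-like cells, and −2.85 for type I interferon and −0.84 for MHC class II in monocyte- or macrophage-like cells. Called doublets kept gave −1.08 for MHC class II and 0.59 for the tumor-associated macrophage list in the latter, and 0.19 for chemokines and 0.30 for inflammatory genes in pDC-like cells. At least 500 genes gave −0.54 for type I interferon and −0.05 for the Treg list in T-cell-like cells. The limit of 30% gave −0.64 for type I interferon, 0.57 for the cytotoxic, 1.35 for the checkpoint and 0.63 for the naive list in T-cell-like cells, −0.85 for MHC class II in monocyte- or macrophage-like cells, 0.00 for apoptosis in B-cell-like, −0.02 for complement in cDC1-like and 0.10 for chemokines in pDC-like cells. Members with at least 100 UMIs gave 0.50 for checkpoint genes in T-cell-like, 0.06 for B cell activation in B-cell-like and −0.04 for the macrophage list in pDC-like cells, and every detected member with 0.5 added gave 0.89 for chemokines in pDC-like cells.

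Of named genes whose interval excluded no difference, 1 setting or more turned these. Values whose interval included no difference could turn too, such as Fas and Cd274 in T-cell-like cells, and are not listed here. In B-cell-like cells Eaf2 was at 0.01 and Tnfsf10 at 0.94 with called doublets kept, and at 0.56 and 0.35 with at least 500 genes; Ly6a was at 0.25 with the mean over cells, 0.74 with doublets kept, 0.83 with at least 500 genes and 0.42 with the limit of 30%, and mt-Co3 at −0.01, −0.09, −0.03 and −0.28. Mcm3 was at −0.10 with doublets kept and Fas at 0.11 with the limit of 30%. In T-cell-like cells Ifit1 was at 0.22 with at least 500 genes, where Cd74 was at 0.58 and H2-Eb1 at 0.76; these were at 0.98 and 1.06 with the limit of 30%. Klrg1 in NK- or ILC1-like cells was at 0.01 and C1qb in cDC1-like cells at −0.28 with the limit of 30%, and Hmgb2 and Tap1 in cDC1-like cells at 0.08 and −0.01 with the mean over cells. In monocyte- or macrophage-like cells H2-DMa was at −0.21 and Cd55 at 0.09 with doublets kept, and Psap at 0.01 with scaling by the median ratio. Of 373 named values, 257 stayed inside their intervals with the limit of 30%, 318 with the mean over cells, 324 with at least 500 genes, 309 with doublets kept and 346 with the other scaling.

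The limit of 5% gave no share of B, T, cDC1, cDC2 or pDC classes, and clustering each library on its own gave none of T, cDC1 or cDC2 classes, because no cluster took that name in a library. Depth limits the classes with few cells in a library, such as pDC-like cells (375 and 162 cells), more than monocyte- or macrophage-like cells (744 and 3824 cells).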

Other observations

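Hepatocyte-like cells of the MC38 library and the Car3-led cluster of 86 control cells, which lay outside the comparisons, had Mt1 at 14500 and 2550 CPM, Orm1 at 3240 and 479 CPM, Fgb at 910 and 126 CPM, Hamp at 1640 and 302 CPM, Saa1 at 366 and 6.30 CPM and Alb at 4240 and 3010 CPM, in that order; Car3, Inmt and Hamp2, which lead the control cluster, went the other way. The Saa3-led cluster of 72 MC38 cells had Arg1 at 6380 CPM, Itgam at 920 CPM, Adgre1 at 592 CPM and Ccr2 at 78.8 CPM. The unnamed cluster with T cell and myeloid markers had C1qa at 106 and 911 CPM, Pdcd1 at 2.80 and 61.0 CPM, Foxp3 at 5.6 and 18.8 CPM and Cd209a at 324 and 1.55 CPM in the control and MC38 libraries.

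The labels name a 5' kit, which reads the variable end of receptor transcripts. In T-cell-like cells, T cell receptor beta variable genes held 54 UMIs beside 8914 of the constant genes in the control, 0.602% (0.453 to 0.785) of their sum, and 21 beside 4103 in the MC38 library, 0.509% (0.315 to 0.777), over 35 variable genes. These low shares go against the label, and which end was captured stays open.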
